A study of Mus musculus with 58 samples.

How the data were processed

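The study profiled mRNA of quadriceps muscle from 34 male mice on 58 Affymetrix arrays, in 3 experiments. Experiment 1 held 6 FVB wild-type mice and 6 mice each of the transgenic lines 20b and 41, aged 6 months. Both lines express an expanded CUG repeat RNA in skeletal muscle and are called CUGexp mice. Experiment 2 held 3 mice that lack the muscle chloride channel gene Clcn1 and 3 BALB wild-type mice, aged 3 months. In these 2 experiments each mouse was run on the array pair 430A and 430B. Experiment 3 held 5 mice that lack the splicing regulator gene Mbnl1 and 5 FVB wild-type mice, aged 3 months, on the single array 430 2.0.

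Per the labels, total RNA was extracted with Tri-Reagent and labelled with biotin by an Enzo kit. The deposited values are probe set intensities on a linear scale, made by the authors with GCRMA, whose version and settings were not given. Distributions differed between the experiments, so the experiments look normalised apart. The median intensity of an array was 398.4 to 437.8 on 430A and 30.2 to 34.39 on 430B in experiment 1. In experiment 2 it was 298.5 to 317.3 on 430A and 22.35 to 27.91 on 430B. In experiment 3 it was 9.559 to 11.62. Arrays give no counts, so their number per group limits the precision.

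Intensities were put on the log2 scale. Probe sets with exactly 1 gene symbol in the supplied annotation were kept (34945 of 45037; 932 had several symbols and 9160 had none). Of the probe sets of a gene, the one with the highest mean over the 3 experiments stood for it everywhere, which gave 18193 genes. A gene was tested in an experiment when its probe set reached a log2 value of 5 (an intensity of 32) on at least as many arrays as the smallest group has. This left 12955 genes in experiment 1, 13244 in experiment 2 and 8965 in experiment 3.

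Each experiment was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with 1 mean per group and no covariate. All tests were two-sided. P values were adjusted by Benjamini-Hochberg over all genes tested in the experiment, with 430A and 430B adjusted together, and a gene was called at an adjusted p under 0.05. A group whose mice all lay under an intensity of 32 has no reliable level, so its fold change was computed against 32 and is given as a lower bound. Titles number the mice of each group. The number joins the 430A and 430B arrays of a mouse: across genes measured on both, 16 of 18 mice of experiment 1 and 6 of 6 of experiment 2 were best matched with their own number. Nothing in the titles says that the numbers pair mice between groups, so no block was fitted in the reported tests.

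Gene lists for muscle biology and for markers of other cell types, 28 in all, were written by hand together with the comparisons, the tests and the rule for naming genes before the data were examined. Each list was tested against all other genes with limma camera at a preset correlation of 0.01, then with an estimated correlation and with fry, which asks whether the list's genes move on balance one way without comparing them with other genes. Adjustment was over the lists within a comparison. Called members were counted over all genes and adjusted over the list alone. Genes called higher and lower in line 20b were taken as sets to the other experiments and tested with fry. The change in line 20b was compared with that in line 41, which shares its wild-type mice, against 100 simulated data sets without any change and with the wild-type mice split 3 and 3 in all 20 ways. Overlaps of calls were tested with Fisher's exact test across genes, and genes are not independent replicates.

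The rule for naming took Clcn1, Mbnl1 and Acta1. It took the 10 largest increases and decreases among called genes for each comparison with wild type, and the 5 for line 20b against line 41. Names that are only clone or model identifiers were passed over. It took up to 4 called members of each list with the largest change, and the 10 genes called the same way in line 20b, line 41 and Mbnl1-null with the largest smallest change. Some were left out for length, from the bottom of each order. Genes named outside the rule are marked as chosen after their values were seen.

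Alternatives were quantile normalisation, a median shift, no filter, a filter at log2 7, other probe sets, array weights, other eBayes settings, stricter thresholds, a replicate block, and each mouse left out in turn. Leaving out the wild-type mice 1 and 2 of experiment 1 together was added after seeing the data. A planned test of the difference between the line 20b and Clcn1-null effects was conditional on a shared scale, and it was not run because the scales differ. The same fit was tested on simulated data with 50 changed genes per size: a log2 change of 1 was called for 92% of genes in the layout of line 20b, 40% in that of Clcn1-null and 80% in that of Mbnl1-null. Unchanged genes made up 3.74%, 7.02% and 3.49% of the simulated calls. The noise was independent between genes and fewer genes changed than were called in the data, so these shares are only a guide. Names of genes beside Mreg were read from the RefSeq annotation of GRCm38.p6, the mouse assembly. Figures were drawn with matplotlib from the same values.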

Results

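Quadriceps mRNA was measured on expression arrays in 34 male mice of 7 groups. FVB wild-type, line 41 and line 20b mice (6 each) form experiment 1, BALB wild-type and Clcn1-null mice (3 each) experiment 2, and FVB wild-type and Mbnl1-null mice (5 each) experiment 3. The share of probe sets at or above an intensity of 32 ran from 70.3% to 72.3% per 430A array and from 49.3% to 51% per 430B array in experiment 1. It ran from 69.4% to 71.4% and from 44.7% to 47.8% in experiment 2, and from 35.7% to 36.4% in experiment 3. Values in brackets after a gene are its log2 change, first group minus second, with the standard error (SE) of the limma fit.

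The targeted genes come first. Clcn1, the chloride channel that sets the resting excitability of muscle fibres, read 9.30, 9.54 and 9.39 on the log2 scale in the Clcn1-null mice and 10.96, 10.25 and 11.27 in BALB wild type (-1.42, SE 0.27). Mbnl1, a splicing regulator bound by CUG repeat RNA, read 12.90 to 13.20 in the 5 Mbnl1-null mice and 13.76 to 13.88 in their 5 wild types (-0.73, SE 0.06). Of the other Mbnl1 probe sets, the brighter one in experiment 1 changed by -1.0 in Mbnl1-null mice, below the filter. At this same probe set line 41 was higher than wild type (0.63, SE 0.14, adjusted p = 0.00865) and line 20b was not (0.00, SE 0.14). Line 20b was there below line 41 (-0.63, SE 0.14, adjusted p = 0.011). The position of these probe sets relative to the deleted part of each gene is not known, so residual signal does not check the deletions. Clcn1 was also lower in line 20b (-0.95, SE 0.10, n = 6), line 41 (-0.46, SE 0.10, n = 6) and Mbnl1-null mice (-1.11, SE 0.14, n = 5). At the probe set read first, Mbnl1 was not called in line 20b (-0.02, SE 0.05), line 41 (-0.05, SE 0.05) or Clcn1-null mice (-0.37, SE 0.12, adjusted p = 0.138). Acta1, the skeletal actin gene, was called in no comparison (log2 changes -0.08 in line 20b, -0.02 in line 41, 0.04 in Clcn1-null and 0.00 in Mbnl1-null).

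**Figure D1:**
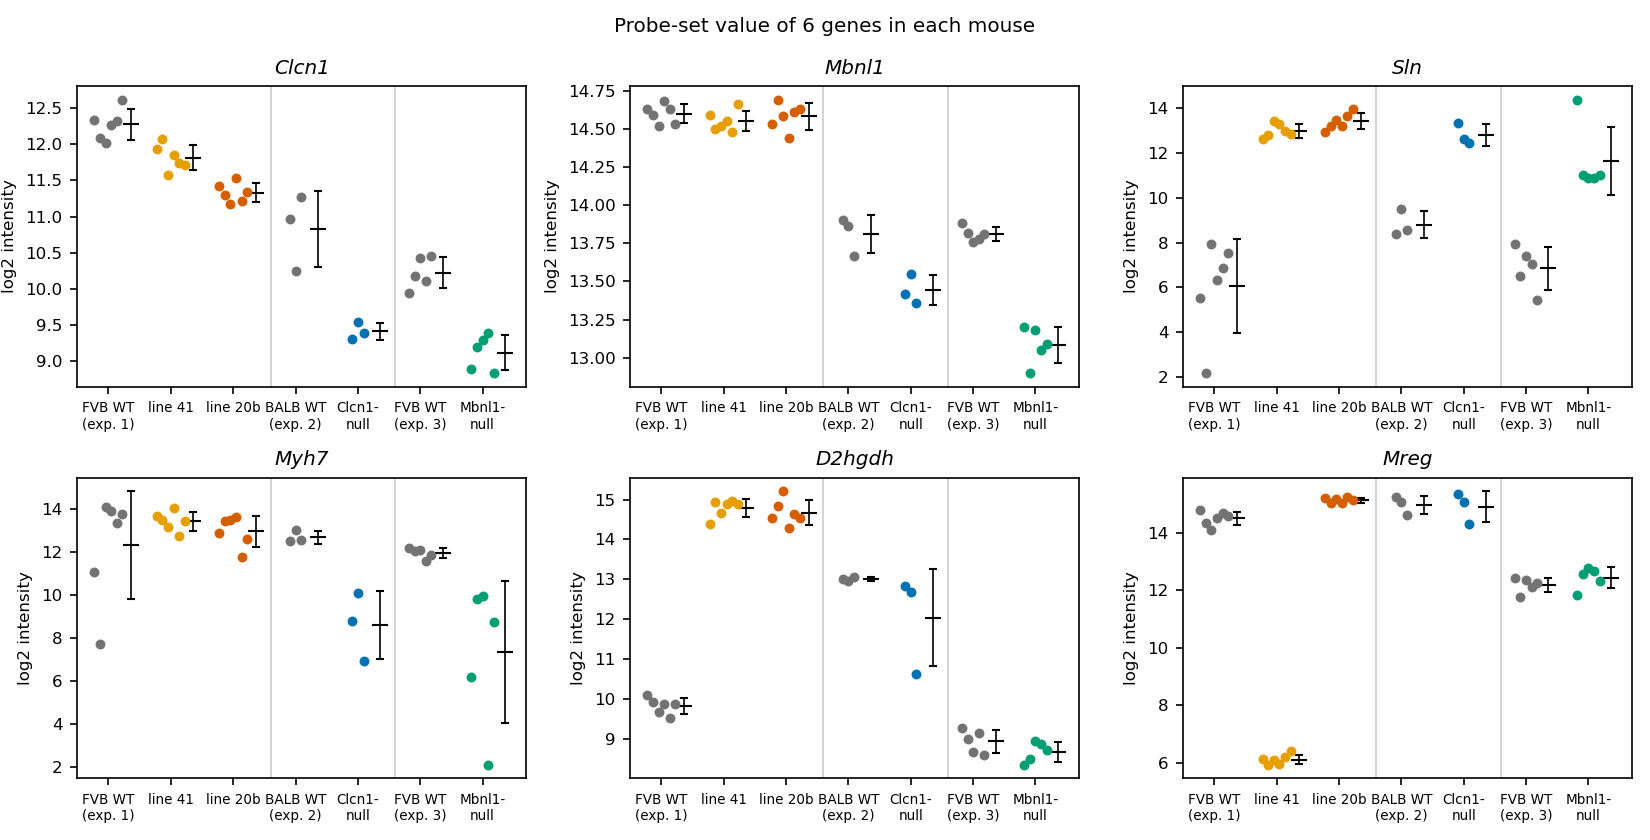
Log2 probe set intensity of 6 genes in each mouse; black marks are group means with the SD, and vertical lines part the 3 experiments. Sln lies above 10 in every mutant mouse and below 10 in every wild-type mouse, and Mreg lies near 6 in line 41 alone.

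Line 20b against FVB wild type asks what expanded CUG RNA does to muscle transcript levels. Sln, encoding sarcolipin, a small inhibitor of the calcium pump of the sarcoplasmic reticulum, rose most (7.34, SE 0.64, 162-fold, n = 6 and 6). Without wild-type mouse 2 its change was 6.56. Uchl1, a ubiquitin hydrolase best known from neurons, rose 25.5-fold (4.67, SE 0.47). Neu2, a cytosolic sialidase (4.45, SE 0.57), Mpzl3 (4.19, SE 0.27), the matrix protein gene Cilp (4.08, SE 0.23) and Atp1b4, a muscle relative of the sodium pump beta subunits (3.86, SE 0.49), rose as well, and the unconventional myosin Myo1a was at least 4.36-fold higher. One probe set of D2hgdh, a mitochondrial dehydrogenase, rose by 4.86 (SE 0.14), while another of the same gene read -0.11. The largest falls were in Kcnab1, a potassium channel beta subunit (-4.68, SE 0.33, 25.6-fold lower), and Kcnf1, a modulatory potassium channel subunit that was at least 9.4-fold lower. Without wild-type mouse 5 that bound for Kcnf1 was 5.69-fold, and another probe set of Kcnf1 read -1.39 (adjusted p = 0.194). The Rac activator Tiam1 (-3.41, SE 0.36), the lipid mediator hydrolase Pla2g7 (-3.24, SE 0.21), and Gdap1, a mitochondrial outer membrane protein gene (-2.99, SE 0.34), fell too. Of the other Gdap1 probe sets 2 were called lower as well (-2.92 and -2.73) and 1 read 0.06. In each of these genes every line 20b mouse lay outside the range of the wild-type mice.

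Genes of muscle function changed in both directions in line 20b. Of 31 measured genes of calcium handling and excitation-contraction coupling, 6 rose, 3 fell and 22 were not called (6 and 5 adjusted over the list alone). After Sln, the largest of these were Camk2d, a calmodulin kinase (1.29, SE 0.13, with other probe sets called at 1.76, 0.80 and 0.68 and 1 not called at -0.20), and the calcium channel subunit Cacng1 (1.09, SE 0.08). Of 21 sarcolemmal channel and pump genes 8 rose and 5 fell (8 and 5 adjusted over the list alone), led by the potassium channel Kcnc4 (1.24, SE 0.11) and Clcn1. Of 22 denervation and junction genes 6 rose and 0 fell (6 and 1 adjusted over the list alone), among them the cell cycle inhibitor Cdkn1a (1.5, SE 0.31), the adhesion molecule Ncam1 (1.14, SE 0.21, with other probe sets not called at 0.50 and 0.45) and the acetylcholine receptor subunit Chrna1 (0.70, SE 0.13). None of these lists was called by camera (adjusted p = 0.432, 0.138 and 0.198), while fry called the channels and pumps (adjusted p = 0.000254). The median (-0.0093) and mean (0.30) of the calcium list differed in sign.

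The slow oxidative fibre list was called higher in line 20b by camera (adjusted p = 0.00298, median 0.58), with 5 of 19 genes higher and 0 lower (5 and 1 adjusted over the list alone). This call is lost with an estimated correlation (adjusted p = 0.834 with an estimated correlation). The members that rose were led by Sln, Smtnl1, a kinase-regulated smoothelin relative (1.77, SE 0.16), Fhl1 (0.77, SE 0.13) and Mybpc1 (0.69, SE 0.07), while Myh7, the slow myosin itself, was not called (0.64, SE 0.79). The mean of the list was 10.97 and 9.607 in wild-type mice 1 and 2 of experiment 1 and 11.92 to 12.73 in the other 4. Without both of them the median of the list was -0.506 and the adjusted p 0.788, and without mouse 2 alone the adjusted p was 0.0833. Fast glycolytic fibre genes were at the threshold (adjusted p = 0.0508, and fry adjusted p = 0.044), with 2 of 21 higher and 5 lower (2 and 6 adjusted over the list alone), led by the glycerol phosphate dehydrogenase Gpd1 (-0.75, SE 0.15) and the Z-disc gene Actn2 (0.74, SE 0.12).

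The fatty acid and glycolysis lists were called lower in line 20b by camera. The oxidative phosphorylation list was not. Of 31 genes of fatty acid uptake and oxidation, 14 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 1.73e-05, median -0.258, and adjusted p = 0.834 with an estimated correlation). Without wild-type mice 1 and 2, 6 fatty acid genes were lower and 1 higher (adjusted p = 0.000297). The examples are the lipoprotein lipase inhibitor Angptl4 (-2.41, SE 0.74), the fatty acid transporter Cd36 (-0.67, SE 0.16) and, upward, the coactivator Ppargc1b (0.66, SE 0.14). Of 30 glycolysis and glycogen genes 10 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.04, and adjusted p = 0.834 with an estimated correlation). Pfkfb3, which makes the main activator of phosphofructokinase, fell by 2.85 (SE 0.28), Fbp2, the muscle fructose bisphosphatase, rose by 1.99 (SE 0.28), and the lactate exporter Slc16a3 fell by 0.96 (SE 0.15). The glycolysis call is lost without any of 5 of the 18 mice, with an adjusted p of at most 0.113, reached without wild-type mouse 3. Of 45 genes of oxidative phosphorylation and the TCA cycle 3 rose and 5 fell (1 and 5 adjusted over the list alone; adjusted p = 0.667).

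Markers of other cell types also differed. Of 23 endothelial and mural cell genes 14 were lower and 0 higher in line 20b (17 and 1 adjusted over the list alone; camera adjusted p = 4.74e-06, median -0.463, and adjusted p = 0.211 with an estimated correlation). Without wild-type mice 1 and 2, 9 were lower and 1 higher (adjusted p = 5.96e-06). Cldn5, an endothelial tight junction gene (-0.93, SE 0.28), and Tek, the angiopoietin receptor (-0.82, SE 0.11), are examples. Of 18 adipocyte markers 7 were lower and 0 higher (9 and 0 adjusted over the list alone; camera adjusted p = 0.00298, median -1.1, and adjusted p = 0.834 with an estimated correlation), including Adipoq (-1.75, SE 0.47). Wild-type mice 1 and 2 had marker means of 12.81 and 13.22, against 11.02 to 11.53 in the other 4, and without them 1 marker was called and the adjusted p was 0.104. Among 19 fibroblast and tendon genes 3 rose and 4 fell (3 and 5 adjusted over the list alone; adjusted p = 0.849, median -0.089 and mean 0.14), with Cilp and Tppp3 (2.27, SE 0.21) up and Kera, a corneal and tendon proteoglycan (-1.45, SE 0.35), down. Nerve and Schwann cell markers fell in 3 of 12, led by the myelin gene Mal (-1.47, SE 0.33), blood cell markers in 1 of 7, Alas2 (-1.45, SE 0.48), and none of the 3 sex-linked genes was called (adjusted over the list alone, 3, 1 and 0 were lower and none higher; list adjusted p = 0.58, 0.58 and 0.849).

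In all, 2563 of 12955 genes were called in line 20b, 1173 higher and 1390 lower, of which 171 and 137 changed at least 2-fold. Without wild-type mice 1 and 2 the count was 2067. The direction of the majority depends on scaling: quantile normalisation gave 1484 higher and 1166 lower, and a median shift 1474 and 1204.

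Line 41, a second CUGexp line, was set against the same wild-type mice. Sln rose by 6.91 (SE 0.64, 121-fold, n = 6 and 6), and by 6.14 without wild-type mouse 2. Uchl1 rose by 4.77 (SE 0.47) and Rrad, a small GTPase that restrains L-type calcium channels, by 3.80 (SE 0.71), and Myo1a was at least 6.77-fold higher. Cpne2, a calcium-dependent membrane-binding protein gene, rose by 3.33 (SE 0.16) and D2hgdh by 4.98 (SE 0.14) at 1 probe set, with the other at -0.03. Mreg, the gene of the organelle transport protein melanoregulin, fell 333-fold (-8.38, SE 0.10). It read 5.94 to 6.41 in the 6 line 41 mice and 14.11 to 14.78 in wild type. The next largest falls were Kcnf1 (-3.08, SE 0.82, with -2.36 without wild-type mouse 5 and another probe set at -0.82), the cardiac actin gene Actc1 (-2.50, SE 0.18), Kcnab1 (-2.02, SE 0.33) and Tiam1 (-2.02, SE 0.36).

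The gene groups of line 41 were these. Calcium handling and excitation-contraction coupling was called higher (6 of 31 rose and 1 fell; 7 and 2 adjusted over the list alone; camera adjusted p = 0.00827, and adjusted p = 0.743 with an estimated correlation), with Cacng1 (0.81, SE 0.08) and Camk2d (0.75, SE 0.13) next to Sln. Another Camk2d probe set was called at 1.24, and 3 were not (0.63, 0.52 and 0.14). Without wild-type mice 1 and 2, 4 rose and 0 fell (adjusted p = 0.0451). The slow oxidative fibre list was called higher (4 of 19 rose and 0 fell; 5 and 1 adjusted over the list alone; camera adjusted p = 0.00051, and adjusted p = 0.792 with an estimated correlation), with Sln and Smtnl1 (1.00, SE 0.16) at its top. Without wild-type mice 1 and 2 its adjusted p was 0.556 and its median -0.187. Heat shock and protein folding was called higher (5 of 25 rose and 0 fell; 6 and 0 adjusted over the list alone; camera adjusted p = 0.0299, and adjusted p = 0.8 with an estimated correlation), through small heat shock proteins such as Hspb7 (1.00, SE 0.24) and Hspb2 (0.45, SE 0.09). Its adjusted p was 0.202 without wild-type mice 1 and 2, and the call is lost without any of 4 single mice, with 0.166 at most, without wild-type mouse 6. Endothelial and mural cell markers were lower in 9 of 23 and higher in 0 (15 and 0 adjusted over the list alone; camera adjusted p = 8.14e-08, and adjusted p = 0.0896 with an estimated correlation), for example the pericyte channel Kcnj8 (-0.92, SE 0.18) and VE-cadherin, Cdh5 (-0.87, SE 0.20, with another probe set at -0.31). Macrophage and leukocyte markers were called higher as a list (adjusted p = 0.0271, and adjusted p = 0.792 with an estimated correlation), though Cd68, a macrophage marker (1.46, SE 0.39), was the 1 of 25 called (1 adjusted over the list alone), and the call is lost without any of 5 mice, with an adjusted p of 0.11 at most, without line 41 mouse 3. Fatty acid genes were not called as a list in line 41 (1 of 31 rose and 1 fell, the same numbers adjusted over the list alone; adjusted p = 0.472).

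In line 41, 1223 of 12955 genes were called, 514 higher and 709 lower, with 72 and 37 changed at least 2-fold. Without wild-type mice 1 and 2, 792 were called, and scaling turned the majority (731 higher and 522 lower after a median shift, 649 and 645 after quantile normalisation).

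The direct comparison of the lines asks where their effects differ. Apart from Mreg (9.02, SE 0.10), line 20b exceeded line 41 most in the imprinted noncoding RNA Meg3 (2.92, SE 0.30), the liver-type glycogen synthase Gys2 (2.50, SE 0.58), Col24a1 (2.31, SE 0.51) and Neu2 (2.27, SE 0.57). It was lower in Kcnab1 (-2.65, SE 0.33), Hmga2-ps1 (-2.21, SE 0.36), Gdap1 (-1.83, SE 0.34), Pfkfb3 (-1.81, SE 0.28) and the amino acid transporter Slc38a4 (-1.76, SE 0.31), and in Clcn1 (-0.49, SE 0.10). Other Meg3 probe sets were called at 2.63, 2.42, 2.17 and 2.05, and 4 were not called (-0.06 to 0.30). Other Gdap1 probe sets were called at -2.32 and -1.78, and 1 read 0.14. In all, 753 genes differed, 451 higher and 302 lower in line 20b, with 44 and 22 at least 2-fold, and 1272 when every probe set was tested separately.

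The fatty acid, glycolysis and fast fibre lists were called lower in line 20b than in line 41. Fatty acid genes were lower in 5 of 31 and higher in 0 (10 and 1 adjusted over the list alone; camera adjusted p = 3.06e-07, and adjusted p = 0.687 with an estimated correlation), led by the beta-oxidation enzyme Hadha (-0.58, SE 0.09) and the fatty acid binding protein gene Fabp3 (-0.52, SE 0.14, with another probe set at -0.07). Glycolysis and glycogen genes were lower in 5 of 30 and higher in 2 (11 and 2 adjusted over the list alone), led by Pfkfb3 and Fbp2 (1.05, SE 0.28). Fast fibre genes were lower in 5 of 21 and higher in 1 (8 and 2 adjusted over the list alone), led by Gpd1 (-0.70, SE 0.15) and the myosin kinase Mylk2 (-0.44, SE 0.10). Both lists had a camera adjusted p of 0.00128, and an adjusted p = 0.687 with an estimated correlation. Macrophage and leukocyte markers (25 measured, camera adjusted p = 0.00128, and adjusted p = 0.83 with an estimated correlation) and adipocyte markers (18 measured, camera adjusted p = 0.0487, and adjusted p = 0.988 with an estimated correlation) were lower in line 20b as lists, with no single gene called over all genes or adjusted over the list alone. The adipocyte call is lost without any of 10 of the 18 mice, with an adjusted p of at most 0.435, reached without line 41 mouse 5.

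The changes in both lines went together. Of 886 genes called in both, 882 had the same direction. Of these 385 were higher in both, where independent calls would give 46.5, and 497 were lower in both, where they would give 76.1. The lines share their wild-type mice, so their calls are not independent. The overlap that sharing alone would give was not computed. Across the 12955 genes the log2 changes correlated at r = 0.779 (Spearman rho 0.691; jackknife SE over the mice 0.0482). Shared wild-type mice alone produced r = 0.499 in simulated data without change. With the wild-type mice split 3 and 3 between the lines, r was 0.602 on average (0.501 to 0.671). The covariance, 0.0987 observed and 0.0116 simulated, was 0.0845 on average with split controls.

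Mbnl1-null against FVB wild type asks what loss of this splicing regulator does. Sln rose by 4.77 (SE 0.68, 27.3-fold, n = 5 and 5), and by 4.09 without Mbnl1-null mouse 1. Uchl1 rose by 4.02 (SE 0.38) and Eda2r, an ectodysplasin receptor, by 3.96 (SE 0.38), and Rrad was at least 5.07-fold higher. Ankrd1, a stress-responsive titin-binding repressor, rose by 3.65 (SE 0.64), Atp1b4 by 3.65 (SE 0.33), the embryonic and atrial myosin light chain Myl4 by 3.52 (SE 0.36) and Cpne2 by 3.49 (SE 0.33). The slow myosin heavy chain Myh7 fell (-4.61, SE 1.25), and its change was -3.30 without Mbnl1-null mouse 4. Its log2 values were 6.17, 9.79, 9.93, 2.09 and 8.71 in the Mbnl1-null mice and 11.57 to 12.19 in wild type. Kcnab1 (-4.43, SE 0.24), Hmga2-ps1 (-4.26, SE 0.53), the slow tropomyosin gene Tpm3 (-3.73, SE 0.58, with another probe set called at -3.52 and others not called at 0.00, 0.10 and 0.13) and the slow troponin genes Tnnc1 (-3.55, SE 0.62) and Tnnt1 (-3.20, SE 0.59, and -2.61 without Mbnl1-null mouse 4) fell as well.

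The slow oxidative fibre list split in Mbnl1-null mice: of 18 genes 4 rose, led by Sln, and 7 fell, among them Myh7, Tpm3 and Tnnc1 (7 and 7 adjusted over the list alone; adjusted p = 0.946, median 0.01 and mean -0.62). Of 22 genes of regeneration and embryonic muscle 9 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.000259, and adjusted p = 0.0425 with an estimated correlation), with Ankrd1, Myl4, embryonic myosin Myh3 (1.89, SE 0.19) and nestin, Nes (1.66, SE 0.29). It was the 1 list call of any comparison that held with an estimated correlation. Collagen and matrix genes rose in 15 of 39 and fell in 0 (20 and 0 adjusted over the list alone; camera adjusted p = 4.15e-06, and adjusted p = 0.876 with an estimated correlation), for example periostin, Postn (1.39, SE 0.21), and Col14a1 (1.33, SE 0.23). Beside them, of 18 fibroblast and tendon markers 5 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.067, median 0.167). Interferon and RNA sensing genes rose in 6 of 12 and fell in 0 (7 and 0 adjusted over the list alone; camera adjusted p = 0.00586, and adjusted p = 0.874 with an estimated correlation), led by the double-stranded RNA sensor Ifih1 (1.34, SE 0.23) and Ifit2 (0.99, SE 0.22). Only these 12 of the list's 31 genes with a probe set passed the filter. The filter lets in genes that are dim in wild type but brighter in Mbnl1-null mice. Ifit2 averaged 4.75 in wild type and 5.73 in Mbnl1-null mice, near the filter at log2 5. In line 20b none of 21 such genes rose and 3 fell (0 and 3 adjusted over the list alone; adjusted p = 0.58), 1 of them, Stat2, near background in both groups. The difference between the experiments was not tested. Macrophage and leukocyte markers rose in 6 of 22 and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0102, and adjusted p = 0.876 with an estimated correlation), led by Cd68 (1.91, SE 0.40) and the galectin Lgals3 (1.79, SE 0.26). This call is lost without either of 2 mice, with an adjusted p of 0.134 at most, without Mbnl1-null mouse 1. Fatty acid genes were called lower (1 of 31 rose and 4 fell, the same numbers adjusted over the list alone; camera adjusted p = 0.0192, and adjusted p = 0.876 with an estimated correlation), including the transporter Slc27a1 (-0.66, SE 0.12). This one too is lost without either of 2 mice, with 0.118 at most, without Mbnl1-null mouse 1.

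Other groups in Mbnl1-null mice were not called by camera, though fry called 2 of them. Of 38 muscle transcripts known to be spliced by MBNL1, 2 rose and 6 fell (2 and 7 adjusted over the list alone; adjusted p = 0.164, and fry adjusted p = 0.00637), with the formin Fhod1 (-1.66, SE 0.12), Camk2b (1.14, SE 0.09) and Clcn1 at the top. Of 41 RNA-binding protein genes 3 rose and 8 fell (3 and 8 adjusted over the list alone; adjusted p = 0.172), led by Celf2 (-0.97, SE 0.12, with other probe sets called at -1.13, -0.87 and, upward, 0.50) and the splicing factor Rbfox1 (-0.75, SE 0.14). Of 19 denervation and junction genes 5 rose, with Cdkn1a (2.19, SE 0.34) and Ncam1 (1.60, SE 0.19) after Ankrd1, and 0 fell (5 and 1 adjusted over the list alone; adjusted p = 0.108, and fry adjusted p = 0.0332). Of 20 clock genes 3 fell and 0 rose (3 and 0 adjusted over the list alone; adjusted p = 0.164), led by Ciart (-1.70, SE 0.31). Of 7 polyamine genes Smox, spermine oxidase, fell (-1.79, SE 0.33) and Sat1, which acetylates polyamines for export, rose (1.26, SE 0.11), with 2 lower and 1 higher adjusted over the list alone (adjusted p = 0.946, median 0.13 and mean -0.059). In all, 1462 of 8965 genes were called, 728 higher and 734 lower, 177 and 110 of them at least 2-fold.

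**Figure D2:**
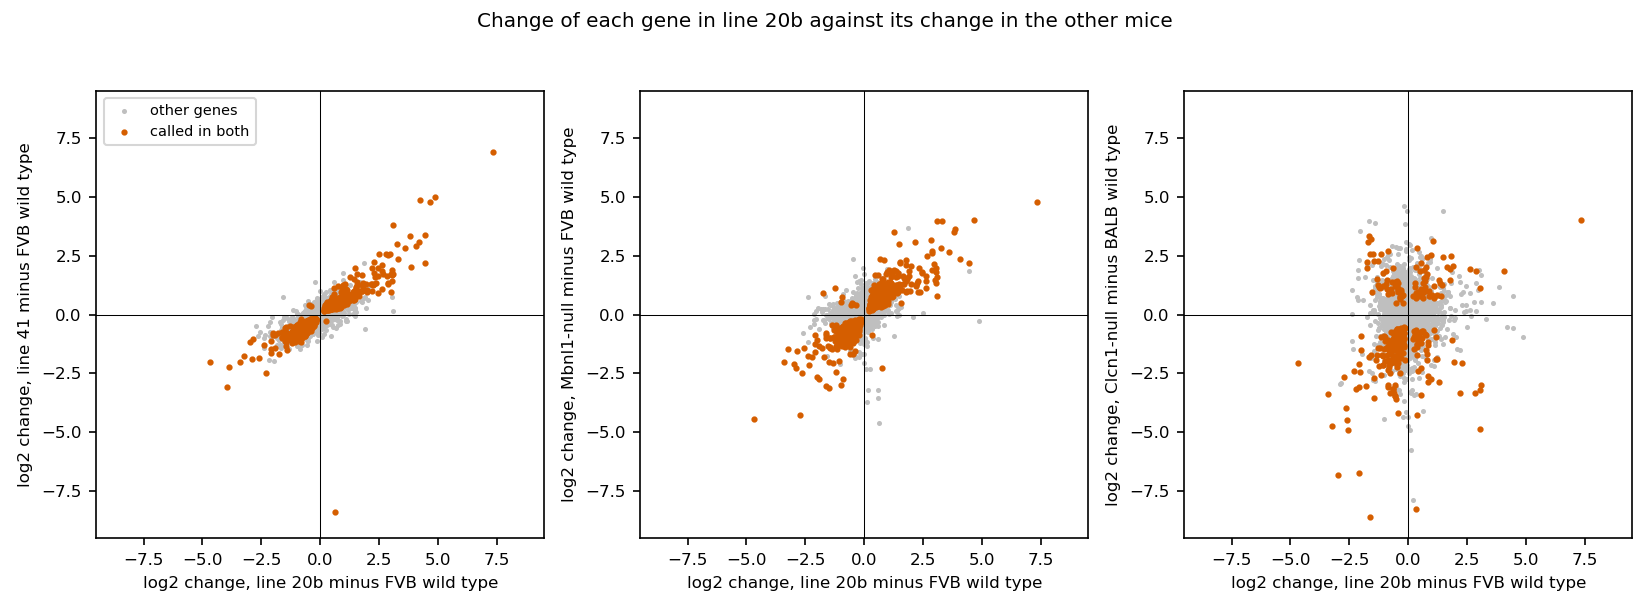
Log2 change of each gene in line 20b (horizontal axis) against its change in line 41, Mbnl1-null and Clcn1-null mice (vertical axes), with genes called in both comparisons in orange. The correlation across genes was 0.779, 0.652 and 0.142, and the first panel shares its wild-type mice between the axes.

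The overlap of line 20b with Mbnl1-null mice addresses how far the CUGexp changes resemble loss of Mbnl1. Of 947 genes called in both, 937 changed the same way: 444 higher in both, where independent calls would give 85.3 (Fisher's exact p = 2.44e-257), and 493 lower in both, where they would give 110 (Fisher's exact p = 1.82e-258). The log2 changes correlated at r = 0.652 across 8909 genes (Spearman rho 0.591, jackknife SE over the mice 0.0571), with no shared mice. Age (6 and 3 months) and array type also differed between these experiments. Genes higher in line 20b had a median of 0.337 in Mbnl1-null mice and 978 of 1054 were above 0 (fry p = 1.01e-05, 10 mice; camera p = 0.000704 with an estimated correlation). Genes lower in line 20b had a median of -0.312 and 1178 of 1332 were below 0 (fry p = 0.00016, 10 mice; camera p = 0.00574 with an estimated correlation).

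The log2 changes of line 41 and Mbnl1-null mice correlated at r = 0.456, with 419 of 430 genes called in both changed the same way (207 higher, where independent calls would give 37.9, and 212 lower, where they would give 56.7). Across line 20b, line 41 and Mbnl1-null mice, 404 of 408 genes called in all 3 changed in a single direction, 204 higher and 200 lower. Those with the largest smallest change were Sln, Uchl1, Cpne2, Rrad, Fam171b, Plekho1, Mustn1, Eda2r, Cilp and Neu2, all higher. Mustn1, a small nuclear protein of the musculoskeletal system, rose by 2.88 (SE 0.30), 2.52 (SE 0.30) and 2.61 (SE 0.22) in line 20b, line 41 and Mbnl1-null mice, and Plekho1, a regulator of membrane signalling, by 3.61 (SE 0.29), 2.81 (SE 0.29) and 2.65 (SE 0.20). Fam171b rose by 3.25 (SE 0.46), 2.99 (SE 0.46) and 2.83 (SE 0.40). These counts leave out genes not called or not tested in Mbnl1-null mice, while 882 genes were called the same way in both lines. Genes outside the common pattern include Mreg, D2hgdh and Actc1, chosen here after their values were seen. In Mbnl1-null mice Mreg changed by 0.25 and the D2hgdh probe set by -0.26. Actc1 fell in line 20b (-2.29) and line 41 (-2.5). It read 12.59 to 14.25 in Mbnl1-null mice and 12.48 to 14.34 in their wild types.

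Clcn1-null against BALB wild type asks what lifelong myotonia (delayed relaxation from loss of the chloride channel) does without CUG RNA. Rarres1, a retinoid-responsive carboxypeptidase inhibitor relative, rose most (5.77, SE 0.73, 54.6-fold, n = 3 and 3), and its change was 6.59 without Clcn1-null mouse 3. It was followed by the acyl-CoA synthetase Acsm3 (4.6, SE 0.67, and 5.36 without the same mouse), the adhesion receptor Adgrg2 (4.37, SE 0.79, and 5.08 without BALB mouse 2), Sln (4.00, SE 0.37) and Hacd2, of very long chain fatty acid synthesis (3.97, SE 0.30). Haptoglobin, Hp (3.90, SE 0.58), and the lipid droplet gene Cidea (3.55, SE 0.62) rose as well. Mettl11b, an N-terminal methyltransferase, was at least 269-fold lower and Neto2, a receptor accessory subunit, at least 58.7-fold lower, with another Neto2 probe set at -3.44 (adjusted p = 0.183). Mss51, a mitochondrial protein gene of fast muscle, fell by 7.88 (SE 0.37), Gdap1 by 6.80 (SE 0.40) and Cdh4 by 6.71 (SE 0.95). Another Gdap1 probe set read -0.71 (adjusted p = 0.252) and another Cdh4 probe set 0.28, and without Clcn1-null mouse 1 the change of Cdh4 was -7.79. In each of these genes the groups did not overlap, which chance gives in 10% of genes with 3 against 3.

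Adipocyte markers rose in Clcn1-null mice: 11 of 18 were higher and 0 lower (14 and 0 adjusted over the list alone; camera adjusted p = 1.2e-10, median 1.81, and adjusted p = 0.437 with an estimated correlation). After Cidea came the hormone-sensitive lipase Lipe (3.32, SE 0.27, with another probe set at -0.17), Cidec (3.20, SE 0.31) and Cebpa (2.58, SE 0.25). Beside this rise stand fatty acid genes, higher in 4 of 31 and lower in 0 (the same numbers adjusted over the list alone; camera adjusted p = 0.000381, and adjusted p = 0.437 with an estimated correlation), led by Slc27a1 (1.99, SE 0.35) and the enoyl-CoA hydratase Echs1 (0.69, SE 0.10). Oxidative phosphorylation and TCA cycle genes were higher in 2 of 45 and lower in 0 (1 and 0 adjusted over the list alone; camera adjusted p = 0.000802, and adjusted p = 0.527 with an estimated correlation), Idh2 (1.36, SE 0.17) first. Collagens and matrix were higher in 2 of 39 and lower in 0 (2 and 0 adjusted over the list alone; camera adjusted p = 0.000515, and adjusted p = 0.469 with an estimated correlation), namely Postn (1.61, SE 0.17) and Bgn (1.53, SE 0.23).

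Calcium handling was called lower in Clcn1-null mice: 7 of 32 fell and 2 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.0294, and adjusted p = 0.437 with an estimated correlation). Sln and the slow and cardiac calsequestrin Casq2 (2.02, SE 0.34) rose, and Jph2, which holds the triad together (-1.73, SE 0.19), fell. Regeneration and embryonic muscle genes were higher in 5 of 24 and lower in 1 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0492, and adjusted p = 0.437 with an estimated correlation), with Myh3 (3.13, SE 0.22) up and Actc1 (-2.38, SE 0.42) down. Matrix proteases and TGF-beta genes had 1 of 23 higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.0475, and adjusted p = 0.437 with an estimated correlation), Mmp2 (1.03, SE 0.17) and Smad3 (-0.94, SE 0.19, with another probe set at -0.30). Endothelial and mural markers had 1 of 23 higher, Acta2 (0.64, SE 0.12), and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.0294, and adjusted p = 0.437 with an estimated correlation). Calcium handling and regeneration lose the call without any of 2 and 5 of the 6 mice (adjusted p of 0.091 and 0.12 at most, without Clcn1-null mouse 1), and matrix proteases and endothelium without any of 4 and 3 (0.125 and 0.0605 at most, without BALB mouse 1). Of 20 slow oxidative fibre genes 6 rose and 8 fell (7 and 8 adjusted over the list alone; adjusted p = 0.828, median 0.12 and mean -0.25). Myh7 (-4.11, SE 0.75, and -3.27 without Clcn1-null mouse 3), Tnni1 (-3.40, SE 0.62, and -2.71 without the same mouse) and Tpm3 (-3.35, SE 0.63, and -2.63 without that mouse) fell and Sln rose. Another Tpm3 probe set was called at -2.79, and 3 were not (-0.21, -0.07 and 0.44). Of 21 channel and pump genes 2 rose and 4 fell (the same numbers adjusted over the list alone; adjusted p = 0.704), among them the sodium pump subunit Atp1b2 (-2.28, SE 0.26, with another probe set at -0.37) and Kcnc4 (-1.88, SE 0.16, with another probe set at -0.41).

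In all, 768 of 13244 genes were called in Clcn1-null mice, 322 higher and 446 lower, with 209 and 296 changed at least 2-fold. The count depends on single mice: it was 488, 302 and 1597 without Clcn1-null mouse 1, 2 and 3, and 145, 287 and 120 without BALB mouse 1, 2 and 3, and array weights gave 2943. Genotype, strain and experiment change together between this comparison and the others. Age changes too against the CUGexp lines (3 months against 6). Differences between the comparisons were therefore not tested.

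**Figure D3:**
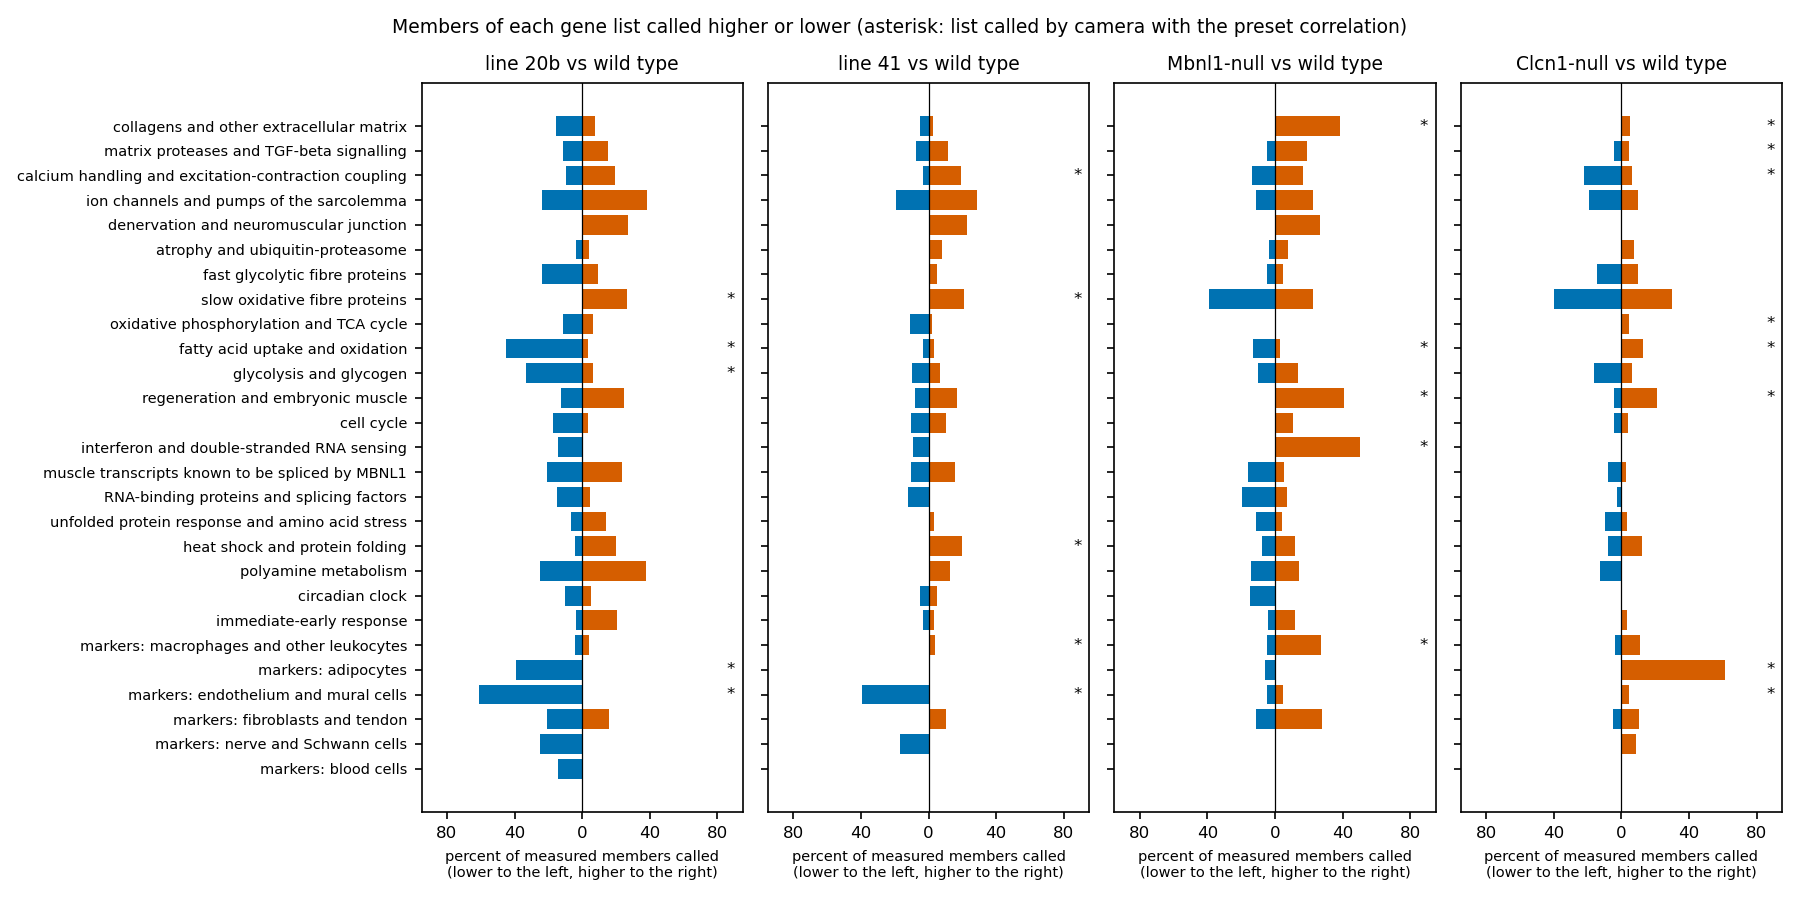
Percent of the measured members of 27 gene lists called higher (orange, to the right) or lower (blue, to the left) in each mutant against its wild type; an asterisk marks a list called by camera with the preset correlation. The adipocyte bar points to the right in Clcn1-null mice (11 of 18) and to the left in line 20b (7 of 18, and 1 of 18 without wild-type mice 1 and 2).

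Line 20b was set beside Clcn1-null mice to see which CUGexp changes also come with myotonia alone. Of 330 genes called in both, 236 had the same direction (56 higher, where independent calls would give 29.1, and 180 lower, where they would give 50.3) and 94 the opposite one. The log2 changes correlated at r = 0.142 across 12030 genes. Those of Mbnl1-null and Clcn1-null mice correlated at r = 0.388 across 8876, with 216 of 243 genes called in both changed the same way. Genes higher in line 20b had a median of 0.02 in Clcn1-null mice with 588 of 1143 above 0 (fry p = 0.73, 6 mice; camera p = 0.765 with an estimated correlation). Genes lower in line 20b had a median of -0.30 with 935 of 1367 below 0 (fry p = 0.043, 6 mice; camera p = 0.18 with an estimated correlation). Both depend on single mice or on scaling: without Clcn1-null mouse 3 the fry p of the first set was 0.0087, and quantile normalisation made it 0.0131. That of the second was 0.106, 0.105 and 0.125 without BALB mouse 1, 2 and 3, and 0.0579 and 0.0564 without FVB wild-type mouse 4 and 6 of experiment 1. Sln rose in every mutant, and Pla2g7, Gdap1 and Smox fell in both line 20b and Clcn1-null mice: Pla2g7 (-3.24 and -4.71), Gdap1 (-2.99 and -6.80, with 1 of its other probe sets at 0.06 and -0.71) and Smox (-2.20, SE 0.24 and -3.18, SE 0.14). Kcnc4 rose in line 20b and fell in Clcn1-null mice.

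**Figure D4:**
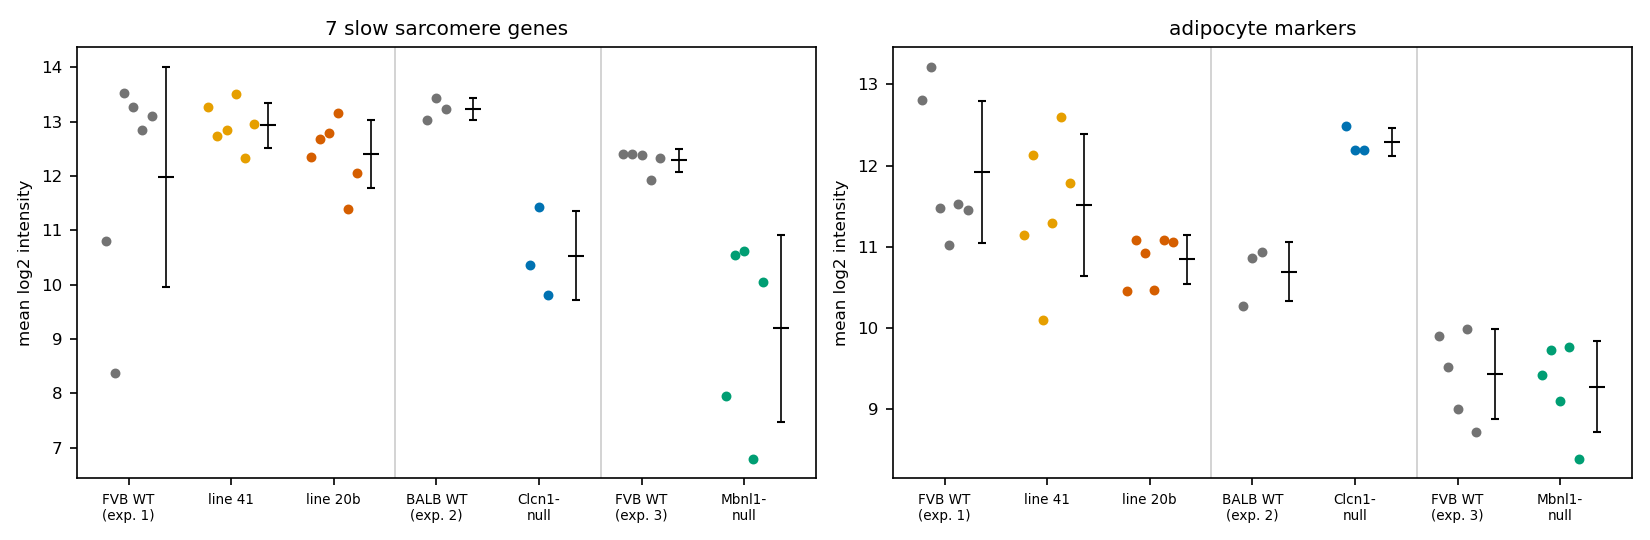
Mean log2 intensity of 7 slow sarcomere genes, chosen after their values were seen (left), and of the adipocyte markers (right) in each mouse; black marks are group means with the SD, and vertical lines part the 3 experiments. FVB wild-type mice 1 and 2 of experiment 1 stand apart from the other wild-type mice of that experiment in both panels, with adipocyte means of 12.81 and 13.22. The adipocyte means of line 41 spread as widely (10.1 to 12.6, SD 0.875, against an SD of 0.878 in that wild type).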

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

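The test of the genes beside Mreg was chosen only after the result was seen. Other Mreg probe sets were examined because Mreg stood out in these data, with the prediction written before that test was run. The prediction for regrouping the mice was also written before it was run. Lines 20b and 41 differed in the tested comparison of one with the other in 753 genes, which counts as a difference between groups. The log2 differences, line 20b minus line 41, were 9.02 for Mreg, 2.92 for Meg3, 2.50 for Gys2, 2.31 for Col24a1 and 2.27 for Neu2. They were -2.65 for Kcnab1, -2.21 for Hmga2-ps1, -1.83 for Gdap1, -1.81 for Pfkfb3 and -1.76 for Slc38a4.

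Mreg was lower in line 41 than in wild type (-8.38) and line 20b. No other Mreg probe set passed the filter (0 of them), so a failing probe set and a fall of the transcript cannot be told apart by a second reading. A change of the whole chromosomal neighbourhood is argued against: of the 20 nearest tested genes, 2 were called lower in line 41, among them Igfbp5 (-0.77), and 1 higher, Lancl1 (0.55), named here after their values were seen. A change at the Mreg locus itself in this line may account for the fall, which no value here tests.

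Whether a random grouping gives as many called genes was tested by regrouping the mice. Of 100 splits each, the real one included, 1 gave as many genes as the real split of line 20b (2563, highest other 220), line 41 (1223, highest other 73), line 20b against line 41 (753, highest other 8) and Mbnl1-null mice (1462, highest other 3). A random grouping is thus unlikely to give these counts, and 1 in 100 is the smallest share the splits allow. Differences between the groups other than genotype are not tested by regrouping. The 6 mice of the Clcn1-null experiment allow 10 splits, too few for a share under 0.05; the real count was 768 and the highest other 0.

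A gap between 1 mouse and the rest of its group, as a share of the group's range, exceeded Dixon's critical value in 22 of 332 sets of values (6.63%), where chance gives about 1 in 20. The sets were genes named in the text, mostly picked by their calls, and the slow sarcomere mean, so that share is only a guide. Groups of 3 mice were too small for the test, so experiment 2 was not covered. In line 20b mouse 3 Cdkn1a was high (0.641), and Chac1 (0.805), Col24a1 (0.75) and Echs1 (0.722) were low. Other line 20b mice stood apart in Col14a1 (0.68, mouse 1 low), Myl4 (0.727, mouse 2 low), Fbp2 (0.719, mouse 5 high) and Gdap1 (0.639, mouse 6 low). In line 41, mouse 6 was low in Hadha (0.74), Jph2 (0.662) and Tiam1 (0.744), mouse 2 in Tppp3 (0.89) and mouse 3 in Cdh5 (0.642). Among the wild-type mice of experiment 1, mouse 2 was high in Slc27a1 (0.629) and low in Slc38a4 (0.68) and Tppp3 (0.752), and mouse 4 was low in Lgals3 (0.658). In experiment 3, wild-type mouse 3 was low in Ifih1 (0.805) and mouse 4 in the mean of the slow sarcomere genes (0.86). Mbnl1-null mouse 1 was high in Sln (0.962), at 14.37 against 11.02 for the next mouse, and in Cdkn1a (0.721), and mouse 5 was low in Col14a1 (0.779).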

How the results depend on the processing

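Leaving out wild-type mice 1 and 2 of experiment 1 together was chosen only after the result was seen, and so was leaving out mice for the gene lists; the other tests were planned. Of the named genes no called change turned its sign under any alternative but another probe set. Counts of called genes stayed within 1.5 times under the other filters, scalings, eBayes settings and adjustments, with these exceptions. An adjusted p under 0.01 left 1468 genes in line 20b, 502 in line 41, 253 between the lines, 173 in Clcn1-null and 659 in Mbnl1-null mice, and a 2-fold minimum left 308, 109, 66, 505 and 287, since both ask for more. Testing every probe set gave 1272 genes between the lines. Leaving out wild-type mice 1 and 2 gave 792 in line 41. In Clcn1-null mice array weights gave 2943. A block by replicate number gave 253 there. Same-number mice of different groups correlated at -0.19 to 0.35 in experiment 1 (6 of 18 pairs over 0.1). The range was -0.18 to 0.075 in experiment 2 (0 of 3) and 0.028 to 0.42 in experiment 3 (4 of 5). The means were 0.059, -0.034 and 0.18, against -0.012, 0.015 and -0.046 for mice of other numbers. A pairing by number is therefore not excluded, least of all in experiment 3. The cause was not tested for the counts of 1272, 792, 2943 and 253.

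Without 1 mouse at a time the counts ran from 2205 to 2692 in line 20b, 885 to 1260 in line 41, 503 to 901 between the lines, 120 to 1597 in Clcn1-null and 1034 to 1601 in Mbnl1-null mice. Of the called named genes, 6 of 68 in line 20b, 10 of 47 in line 41, 9 of 31 between the lines, 32 of 47 in Clcn1-null and 3 of 53 in Mbnl1-null mice lost their call without some mouse. Genes higher in line 20b, not called as a set in Clcn1-null mice, had a fry p of 0.0131 after quantile normalisation and 0.0087 to 0.985 without 1 mouse. Genes lower in line 20b, called there, had p = 0.18 by camera with an estimated correlation, and a fry p of 0.0811 with the line 41 genes, 0.117 with the block and 0.0048 to 0.125 without 1 mouse. The cause was not tested. In Mbnl1-null mice the sets kept a fry p from 1.08e-06 to 6.16e-05 and from 2.8e-05 to 0.000728 without 1 mouse. The correlation of lines 20b and 41 was 0.743 to 0.795 without 1 mouse and 0.602 with split controls, which share no mice and are fewer. The cause was not tested.

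Of the 28 list calls, 1 held with an estimated correlation, 8 with fry, 26 without a filter, 24 at log2 7, 25 after quantile normalisation and 28 with the block. Of 164 changes read at other probe sets of called named genes, 89 kept the call and 54 lost it. At least 1 other probe set had the opposite sign, with others that kept it in some of these genes, for D2hgdh (-0.11 in line 20b, -0.03 in line 41), Gdap1 (0.06 in line 20b, 0.14 between the lines), Camk2d (-0.20 and -0.33), Stat2 (0.14 and 0.05) and Celf2 (0.02 in line 20b, 0.03 in line 41 and between the lines, 0.50 in Mbnl1-null). It also did for Lipe (0.12 in line 20b, -0.17 in Clcn1-null), Ncam1 (-0.01 in line 41), Meg3 (-0.06) and Rbfox1 (0.02) between the lines, Cdh4 (0.28) in Clcn1-null, and Tpm3 (0.44 in Clcn1-null, 0.10 and 0.13 in Mbnl1-null). The cause was not tested. The planned difference between the line 20b and Clcn1-null effects was not run, since the scales differ. Signal over background limits the tests: 12955 of 18193 genes passed the filter in experiment 1 and 8965 in experiment 3.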

Other observations

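The test of the strain variant under D2hgdh and the 2 tests of the slow-fibre share at dissection were chosen only after the result was seen. The list tests in this part were planned. The readings of the other D2hgdh probe set and of the fast fibre list address patterns seen in these data. Their predictions were written before those tests were run. No stress list was called by camera in line 20b, Clcn1-null or Mbnl1-null mice. Of 25 heat shock and folding genes, 5 rose and 1 fell in line 20b (7 and 2 adjusted over the list alone; list adjusted p = 0.138), 3 rose and 2 fell in Clcn1-null mice (4 and 5; list adjusted p = 0.247) and 3 rose and 2 fell in Mbnl1-null mice (5 and 5; list adjusted p = 0.946). The small heat shock gene Hspb7 rose in each: by 1.76 (SE 0.24) in line 20b, 1.92 (SE 0.23) in Clcn1-null and 1.41 (SE 0.23) in Mbnl1-null mice. Hsph1, a co-chaperone of the large heat shock family, fell in Clcn1-null mice (-2.37, SE 0.26), and Dnaja1 fell in Mbnl1-null mice (-1.36, SE 0.26). Of the unfolded protein and amino acid stress genes 4 of 29 rose and 2 fell in line 20b (5 and 3 adjusted over the list alone; list adjusted p = 0.667, with mean -0.066 and a test direction of higher) and 1 of 30 rose and 3 fell in Clcn1-null mice (2 and 3; list adjusted p = 0.705). Chac1, which degrades glutathione, fell in both (-2.03, SE 0.68 and -2.45, SE 0.52, with -1.17 in line 20b without mouse 3). Asns, asparagine synthetase, was at least 2.3-fold lower in line 20b and rose in Clcn1-null mice (3.09, SE 0.47). Its line 20b and wild-type values overlapped, and the bound was 1.78-fold and 1.68-fold without wild-type mouse 1 and 2. Of 29 immediate-early genes 6 rose and 1 fell in line 20b (6 and 1 adjusted over the list alone; list adjusted p = 0.198), led by Fos (2.07, SE 0.50).

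Of 29 cell cycle genes 1 rose and 5 fell in line 20b (the same numbers adjusted over the list alone; list adjusted p = 0.53): the inhibitor Cdkn1a was the one that rose, and the related inhibitor Cdkn2c (-1.19, SE 0.18) was among those that fell. Of 26 atrophy and proteasome genes 1 rose and 1 fell in line 20b (1 and 1 adjusted over the list alone; list adjusted p = 0.918), and 2 rose and 0 fell in Clcn1-null mice (7 and 1 adjusted over the list alone; list adjusted p = 0.704, median -0.018 and mean 0.17), the metallothionein Mt1 (2.93, SE 0.48, with another probe set at 0.63) and the transcription factor Foxo1 (1.17, SE 0.22). Of 8 polyamine genes 3 rose and 2 fell in line 20b (4 and 2 adjusted over the list alone; list adjusted p = 0.5, median 0.12 and mean -0.013), with Smox down (-2.20, SE 0.24) and Sat1 up (1.11, SE 0.14).

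D2hgdh was higher by 4.86 and 4.98 in lines 20b and 41 at 1 probe set and not called in Mbnl1-null mice. The other D2hgdh probe set that passed the filter read at most -0.03 in the lines, which goes against a rise read alike by both probe sets. The rise may belong to another transcript read by the first probe set, but no value here identifies one. A sequence variant under the probe set is another candidate explanation: the gap between the probe sets was larger by 2.53 in BALB than in FVB wild type, but strain and experiment change together there, so variant and experiment cannot be told apart. The gap also differed within FVB wild type. The first and the other probe set read 9.818 and 9.944 in experiment 1, and 8.931 and 7.588 in experiment 3, on another array type. A biological difference between the CUGexp lines and wild type at this gene stays open and was not tested further.

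The mean of 7 slow sarcomere genes, Myh7, Myl2, Myl3, Tnnt1, Tnnc1, Tnni1 and Tpm3, differed by -3.09 in Mbnl1-null and by -2.70 in Clcn1-null mice. These genes were chosen after their values were seen, so a test of their mean on the same mice would be void, and the whole slow oxidative list was not called in either (adjusted p = 0.946 and 0.828). In Mbnl1-null mice a similar fall of slow and fast fibre genes is argued against, since the fast fibre list had a median of -0.08. The intensities were normalised, and the fast list lay near the top of the scale (mean 15 in wild type). A loss of all fibre transcripts is therefore not excluded. In Clcn1-null mice a similar fall was not tested. The mean of the fast fibre list was 15.22 (SD 0.235) there and 15.51 (SD 0.0833) in BALB wild type. A different share of slow-fibre muscle at dissection may contribute, since the same mean spanned 5.16 among the 6 wild-type mice of experiment 1, though mice 1 and 2 made that span (10.81 and 8.37, against 12.85 to 13.53) and it was at most 0.49 among the wild-type mice of experiments 2 and 3. A shift of fibre type in the null mice stays open as well, and these data do not choose between them.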
